A study of Sus scrofa with 6 samples.

How the data were processed

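Placental RNA of pig fetuses was sequenced at gestation day 45. Per the labels, 6 pregnant gilts were used, and placentae from 3 dams gave 3 male and 3 female libraries. Each placenta belonged to a different fetus, so the libraries of one sex are separate biological samples. Fetal sex was taken from the labels and is the only grouping they give. Per the labels' protocols, total RNA was extracted with a column kit and sequenced on a NovaSeq instrument as paired reads of 150 bases.

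The deposited table holds raw counts per Ensembl gene, as whole numbers that the authors did not normalize. Per the submitters' processing notes, FastQC, cutadapt, fastp, STAR and edgeR were used with the Sscrofa11.1 genome. Their versions and roles, the read counter and the annotation release are not given in the sources used here. The table lists 34261 genes, of which 12914 had no count in any library. Total counts ran from 34746315 in female placenta 3 to 48758606 in male placenta 2. Among genes with 5 to 20 counts, 75.0% to 79.5% of the values were even numbers, against 48.8% to 51.0% among values above 1000. The totals are 1.74 to 2.44 times the 20000000 paired-end reads per library that the labels state. Whether both reads of a pair were counted is not given. If they were, a fragment adds up to 2 counts, and a floor of 3 fragments lowers the bounds given for EIF1AY, KDM5D and ITIH4 to 252-fold, 12.7-fold and 68.2-fold.

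Low counts were coarse in some libraries. The most frequent low count, smoothed over neighbouring even counts, was 2 in female placenta 1 and male placenta 2, 8 in male placenta 3, 10 in female placenta 2 and male placenta 1, and 16 in female placenta 3. A total count is therefore not a number of independent molecules. The floor of 3 counts, also when taken as 3 fragments of up to 2 counts, lies under this value in female placentae 2 and 3. The folds given as lower bounds could therefore be smaller, and no bound at the coarser steps was computed. Limits based on a count of 0 cover counting error only.

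Gene symbols came from a table pairing Ensembl IDs with symbols, which named 15445 IDs. Chromosomes came from a RefSeq table of Sscrofa11.1, matched by symbol, for 11972 of the genes tested. Of these, 390 lay on chromosome X and 11580 on autosomes. No mitochondrially encoded gene could be followed by symbol, and XIST was not analysed here because no ID carried that name.

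Male and female placentae were compared with edgeR 4.0.16 in R 4.3.3, using TMM normalization, filterByExpr by sex, robust dispersion estimates and the quasi-likelihood F-test. The filter kept 15603 genes. P-values were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. A positive log2 fold change means a higher level in male placentae. Its SE is back-calculated from the test, as the absolute log2 fold change divided by the square root of the F statistic. Where all female libraries were at 0, a fold is given as a lower bound against a floor of 3 counts in each female library, averaged over the 3 as CPM. Levels are CPM values, counts scaled by library size and the TMM factors.

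Before the data were examined, 31 gene lists covering the sex chromosomes, cell types, metabolism, signalling and tissue state were fixed, and 29 had the minimum of 5 tested members. They were tested with camera in limma 3.58.1 at a preset inter-gene correlation of 0.01, and again with an estimated correlation and with fry. The rule for naming genes was also fixed beforehand. It takes every tested Y-linked gene and the genes past the threshold whose sexes do not overlap. If fewer than 5 pass in a direction, it fills up to 5 by the smallest unadjusted p. It adds up to 4 members of each list past the threshold and up to 2 members of other lists. Genes without a symbol are counted but not named.

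The alternatives were other normalizations and filters, DESeq2 1.42.0, limma-voom, the edgeR likelihood ratio test, a replicate block, other thresholds and leaving out each library. After the data were seen, 4 further alternatives were added, namely an edgeR exact test without a filter, counts divided by the most frequent low count of each library, a fit without male placentae 1 and 3, and a list of all X-linked genes. Figures were drawn with matplotlib 3.10.9.

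The test was run on simulated data with 200 changed genes among 14931, drawn from the means and library sizes of these samples. With the dispersion estimated for each gene it recovered 14.0% of genes changed 2-fold, 62.0% of those changed 4-fold, 82.0% of those changed 8-fold and 94.0% of those changed 16-fold, with 7 false calls. All recovered genes had the right sign. The changed genes were drawn only from genes with higher counts, and the coarse low counts were not simulated. These shares therefore do not hold for genes with low counts.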

Results

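Placental transcripts were measured in 3 male and 3 female pig fetuses at gestation day 45, to compare the sexes in a study of fetoplacental metabolism. The pig placenta is a diffuse, non-invasive organ in which the fetal chorion lies against the uterine epithelium. Total counts were 35423559, 46367627 and 34746315 in female placentae 1, 2 and 3, and 39469213, 48758606 and 44225402 in male placentae 1, 2 and 3. Between 16381 and 18130 genes had a count in each library. Libraries of the same sex were as far apart as libraries of different sexes, with a mean Pearson correlation of log2 CPM across genes of 0.905 in both cases.

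Male placentae differed from female placentae in 6 genes by the edgeR quasi-likelihood test, all of them higher in males. The only one with a symbol was EIF1AY (ENSSSCG00000037509), a Y-linked translation initiation factor placed at 9687350 to 9704489 on chromosome Y of Sscrofa11.1. It had 1445, 1492 and 1975 counts in the 3 male libraries and 0 in every female library. Its level was 38.3 ± 4.89 CPM in males (SD, n = 3), at least 504-fold above the female floor (adjusted p = 9.56e-05 by edgeR between the sexes). The other 5 genes carry no symbol, and each had at most 2 counts in any female library. KDM5D, a Y-linked histone demethylase, was also read only in males, with 53, 22 and 179 counts, at least 25.5-fold above the female floor, and 12.6-fold without male placenta 3. It did not pass over all genes (adjusted p = 1.00 by edgeR) and passed when adjusted over the list alone (adjusted p = 0.00177 by edgeR). Counts of both genes therefore followed the sex labels in all 6 libraries.

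X-linked genes as a class were close to equal between the sexes. The 390 tested X-linked genes had a median log2 fold change of -0.020, against -0.0011 for autosomal genes, and none was called. Of the 17 tested X-linked partners of Y genes and genes that escape X inactivation, 13 had a negative log2 fold change, with a median of -0.15. That list did not pass camera (adjusted p = 0.105). Its members with the smallest p were TXLNG at -1.07 ± 0.43 (log2 fold change ± SE) and TRAPPC2 at -0.47 ± 0.21. Neither passed over all genes or over the list alone.

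**Figure D1:**
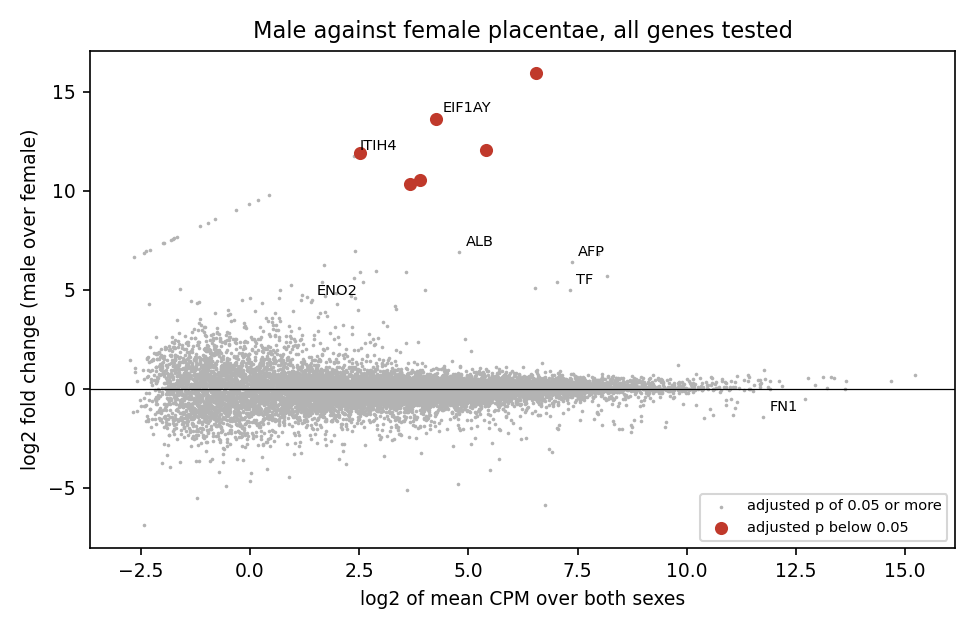
Log2 fold change (male over female, vertical axis) against the log2 of the mean CPM of the 2 sexes (horizontal axis) for the genes tested by edgeR. Red points are the 6 genes with an adjusted p below 0.05, all higher in males, and grey points are the other genes.

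No autosomal gene with a symbol passed the threshold. The genes of smallest unadjusted p, none of which passed (adjusted p from 0.619 to 1.00 by edgeR), included GALC, a lysosomal galactosidase, and LPL, which releases fatty acids from circulating lipoproteins. GALC was at 147 ± 62.1 CPM in males and 59.1 ± 12.9 in females (SD, n = 3 each). LPL was at 38.8 ± 9.56 CPM in males and 17.5 ± 3.58 in females. KIF21A, a kinesin motor, had a log2 fold change of 0.97 ± 0.23 (SE). ENO2, the neuronal form of enolase, had one of 4.40 ± 0.98. It was 3.21 without male placenta 3, in which a list of neuron markers lay 4.02 log2 units above the other libraries. ITIH4, a liver-secreted plasma protein, was read only in males, at 7.72, 2.09 and 21.3 CPM in male placentae 1, 2 and 3. That is at least 136-fold above the female floor, and 64.6-fold without male placenta 3. In the other direction stood ISG12(A), an interferon-induced gene, at -1.55 ± 0.30, and TNNI2, a fast-muscle troponin, at -2.01 ± 0.39. PPP1R3C, a regulator of glycogen synthesis, was at -1.44 ± 0.30. INPP4B, a phosphoinositide phosphatase, was at -1.85 ± 0.41, and the odorant receptor gene OR51E1 at -2.80 ± 0.60. All male values lay on one side of all female values for these 10 genes, which happened for 8.00% of the genes tested, where chance gives 10%.

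The count of genes lower in males was 0 by edgeR, with 359 genes lower and 210 higher at an unadjusted p under 0.05, where chance gives 780. DESeq2 called 20 genes higher and 11 lower, the edgeR likelihood ratio test 20 and 4, and limma-voom 0 in either direction, with 506 at an unadjusted p under 0.05. Without female placenta 1 the edgeR count of lower genes was 31, and without male placenta 2 the count of higher genes was 15.

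Smooth muscle markers were lower in male placentae as a list. All 11 members had a negative log2 fold change, with a median of -1.58 (camera adjusted p = 1.49e-08). With an estimated correlation, which was 0.76, the list did not pass (adjusted p = 0.637). Over the list alone 6 members were lower, against 0 over all genes. These 6 calls were kept without female placenta 1 and lost in each of the other fits without 1 library. ACTA2, smooth muscle actin, was at 136 ± 26.7 CPM in males and 559 ± 467 in females (SD, n = 3 each). TAGLN was at 93.7 ± 13.7 against 281 ± 186, and the actin-binding proteins CALD1 and CNN1 had log2 fold changes of -0.89 ± 0.25 and -2.02 ± 0.61 (SE). Female placenta 2 had the highest list mean, 6.21 log2 CPM, against 4.45 and 5.02 in the other females and 3.55 to 4.53 in males. Without it the list median was -0.67, with ACTA2 at -1.13, TAGLN at -0.91 and CNN1 at -1.04.

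Type I interferon response genes were also lower in males as a list. Of 24 members tested, 18 had a negative log2 fold change, with a median of -0.51 (camera adjusted p = 2.64e-05). With an estimated correlation the list did not pass (adjusted p = 0.221, unadjusted camera p = 0.0076). That estimate was 0.0058, under the preset 0.01, so a higher correlation between members was not the reason. ISG12(A) was at 17.1 ± 7.27 CPM in males and 50.1 ± 5.45 in females (SD, n = 3 each), and IFI6, another interferon-induced gene, at 8.39 ± 2.58 against 23.0 ± 9.85. These 2 were lower when adjusted over the list alone, against 0 over all genes. Of 6 fits without 1 library, ISG12(A) kept this call in 5, losing it without male placenta 3 (adjusted p = 0.0534 by edgeR), and IFI6 in 2, without female placenta 1 and without male placenta 1. IFI44 and IRF9, a transcription factor of the interferon response, had log2 fold changes of -1.35 ± 0.39 and -0.89 ± 0.37 (SE). The list mean was 2.74 to 2.96 log2 CPM in females and 2.34 to 2.37 in males. The exact two-sided permutation p of these means was 0.1, the smallest that 3 against 3 can give, which 3 of the 29 lists reached where chance gives 10%.

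Endothelial markers were the third list lower in males. All 14 members had a negative log2 fold change, with a median of -0.44 (camera adjusted p = 6.63e-05). With an estimated correlation, which was 0.42, the list did not pass (adjusted p = 0.637), and no member passed over all genes or over the list alone. The tight-junction gene CLDN5 was at 25.1 ± 7.23 CPM in males and 42.3 ± 3.86 in females (SD, n = 3 each). SOX18, ENG and TEK, genes of vessel formation, had log2 fold changes of -0.69 ± 0.38, -0.52 ± 0.28 and -0.45 ± 0.25 (SE). Without male placenta 3 the list no longer passed (adjusted p = 0.162), with a median of -0.23.

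Yolk sac and hepatic endoderm markers were higher in males as a list, and high in only 2 of the 3 male libraries. All 9 members tested had a positive log2 fold change, with a median of 4.96 (camera adjusted p = 0.000533). With an estimated correlation, which was 0.92, the list did not pass (adjusted p = 0.732), and no member passed over all genes or over the list alone. Serum albumin, ALB, was at 51.1 CPM in male placenta 1 and 113 in male placenta 3, but at 0.423 in male placenta 2 and 0.177 to 0.725 in females. The iron carrier TF was at 312 and 611 CPM in male placentae 1 and 3, at 3.02 in male placenta 2 and at 4.38 to 18.8 in females. VTN and FGG, a vitronectin and a fibrinogen chain, had log2 fold changes of 2.26 ± 1.01 and 5.41 ± 2.61 (SE). Without male placenta 3 the log2 fold changes were 5.85 for ALB, 4.01 for TF, 1.54 for VTN and 4.44 for FGG. The list no longer passed without male placenta 1, with a median of 4.96 (adjusted p = 0.0708), or without male placenta 3, with a median of 4.01 (adjusted p = 0.147). Its mean level was 5.97 and 6.85 log2 CPM in male placentae 1 and 3, -1.75 in male placenta 2 and -0.041 to 2.58 in females. Erythroid markers had a median of 0.79 and did not pass (adjusted p = 0.157), with list means of 4.82 and 5.50 log2 CPM in male placentae 1 and 3, against 3.33 in male placenta 2 and 3.80 to 4.26 in females. Over the fits without 1 library the erythroid median ran from 0.35 to 1.22 and its camera adjusted p from 1.03e-07 to 0.956.

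**Figure D2:**
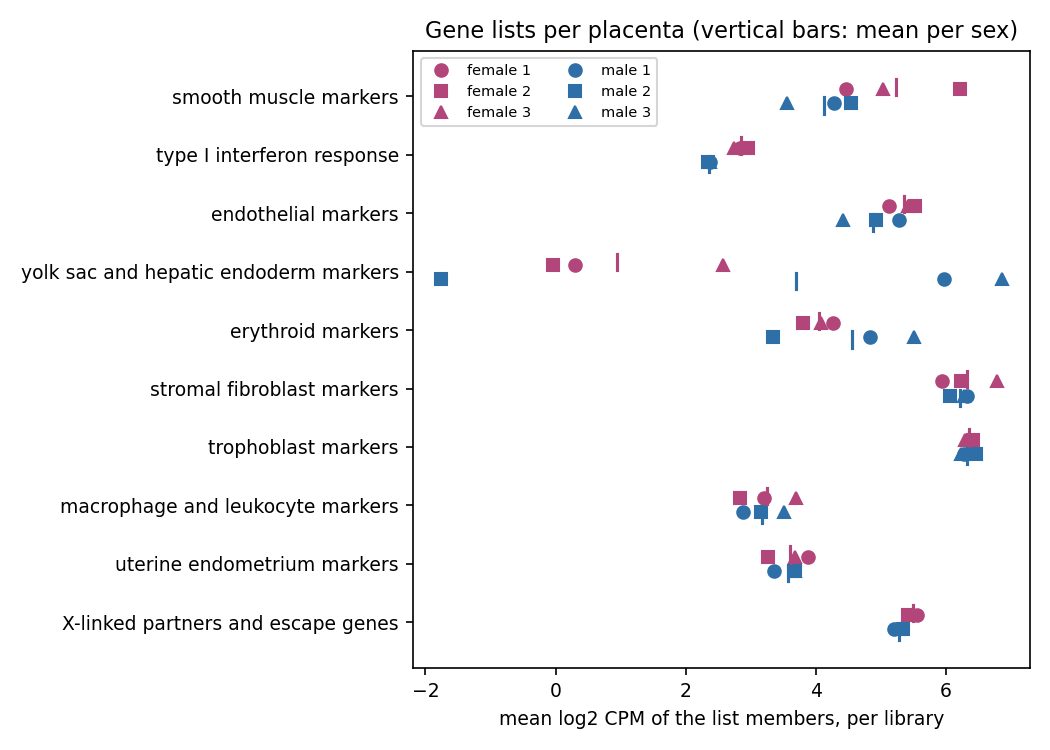
Mean log2 CPM of the members of 10 gene lists in each library (points, coloured by sex, shaped by replicate), with vertical bars at the mean of each sex. The interferon means of the 3 females (2.74 to 2.96) lie above those of the 3 males (2.34 to 2.37), and the hepatic means are high in male placentae 1 and 3 (5.97 and 6.85) and low in male placenta 2 (-1.75).

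None of the lists of metabolic genes passed camera in the main fit. Over the fits without 1 library the camera adjusted p ran from 0.00541 to 0.744 for cholesterol synthesis. It ran from 0.0366 to 0.774 for the tricarboxylic acid cycle. Among 23 glycolysis genes the median log2 fold change was -0.022 (adjusted p = 0.895). ENO2 alone passed when adjusted over the list alone (adjusted p = 0.0325 by edgeR), a call kept only without female placenta 2 and without male placenta 2 among the fits without 1 library. It was at 3.17, 1.18 and 10.7 CPM in male placentae 1, 2 and 3 and 0.143 to 0.408 in females. PFKFB4, a regulator of glycolytic flux, was at -0.76 ± 0.30 (SE). Of 30 amino acid transporters, 22 had a positive log2 fold change, with a median of 0.099 (adjusted p = 0.105). SLC7A5, a carrier of large neutral amino acids, was at 1.08 ± 0.50, and the taurine carrier SLC6A6 at 0.72 ± 0.34. The tricarboxylic acid cycle list had a median of 0.085 (adjusted p = 0.233), with PDHA1 at 0.65 ± 0.31 and ACO1 at 0.57 ± 0.36. The nuclear genes of oxidative phosphorylation had a median of 0.029 (adjusted p = 0.895), with NDUFA1 at -0.62 ± 0.25 and NDUFC1 at -0.34 ± 0.26.

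The 40 genes of fatty acid uptake, storage and oxidation were evenly divided, 20 positive and 20 negative (adjusted p = 0.751). LPL and ACSL4, an acyl-CoA synthetase, led them at 1.15 ± 0.25 and 1.70 ± 0.62 (SE). ACSL4 was at 8.58, 3.54 and 20.6 CPM in male placentae 1, 2 and 3 and 2.23 to 4.71 in females, and its log2 fold change was 0.86 without male placenta 3. Fatty acid synthesis had a median of 0.14 (adjusted p = 0.686), with ELOVL7 at -0.67 ± 0.31 and SCD5 at -1.12 ± 0.58. Cholesterol synthesis had one of 0.18 (adjusted p = 0.233), with PCSK9 at 1.72 ± 0.74 and LDLR at -0.59 ± 0.33. Glucose and fructose transport stood at -0.14 (adjusted p = 0.831), with SLC5A2 at -1.89 ± 1.02 and KHK at -0.65 ± 0.55, or -1.13 and -0.056 without female placenta 3. Steroid hormone synthesis stood at 0.028 (adjusted p = 0.831), with TSPO at -1.20 ± 0.37 and HSD17B2 at 2.91 ± 1.87. HSD17B2 was at 1.24, 0.356 and 4.83 CPM in male placentae 1, 2 and 3, 0.858 in female placenta 1 and 0 in the other females, and its log2 fold change was 1.48 without male placenta 3. Monoamine synthesis and transport stood at 0.043, while its mean was -0.25 (adjusted p = 0.751), with KYNU at -1.78 ± 0.59 and SLC22A3 at -1.06 ± 0.52, or -1.08 and -0.43 without female placenta 3.

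The trophoblast, stromal, leukocyte, endometrial and erythroid marker lists did not pass camera in the main fit. Over the fits without 1 library the stromal camera adjusted p ran from 0.0264 to 0.496. The 24 trophoblast markers had a median of 0.074 (adjusted p = 0.892), with the keratin KRT18 at -0.88 ± 0.30 and the transcription factor TFAP2A at 0.55 ± 0.20 (SE). Stromal fibroblast markers had a median of -0.29 (adjusted p = 0.105), with FN1 at -1.43 ± 0.69, or -0.66 without female placenta 2, and COL1A2 at -0.60 ± 0.31. Leukocyte markers had one of -0.15 (adjusted p = 0.831), with ITGAM at 0.57 ± 0.37 and LYZ at -1.13 ± 0.87, or -0.22 without female placenta 2. Markers of the uterine endometrium, the maternal tissue against which the chorion lies, had one of -0.26 (adjusted p = 0.686), with HOXA10 at -0.55 ± 0.24 and HOXA11 at -0.71 ± 0.31. In the erythroid list, HBQ1 was at -0.83 ± 0.42 and EPB42 at 1.30 ± 0.66.

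Imprinted genes, many of which set placental growth, had a median of -0.0035 (adjusted p = 0.353), with PHLDA2 at -1.06 ± 0.29 and DIRAS3 at 1.94 ± 0.77 (SE), or 0.64 without male placenta 3. Insulin and IGF signalling had one of 0.087 (adjusted p = 0.968), with IGFBP4 at -0.47 ± 0.19 and IGFALS at -0.87 ± 0.42. Angiogenic factors had one of -0.13 (adjusted p = 0.233), with the vasoconstrictor EDN1 at -1.57 ± 0.48 and VEGFA at 0.38 ± 0.20. Hypoxia response genes had one of -0.024 (adjusted p = 0.686), with EGLN3 at -0.85 ± 0.36 and P4HA2 at -0.54 ± 0.24. Pseudoautosomal genes stood at 0.48 (adjusted p = 0.233), with PRKX at 0.80 ± 0.33 and GYG2 at -0.74 ± 0.53. Immediate early and heat shock genes stood at -0.16 (adjusted p = 0.205), with KLF6 at -0.54 ± 0.17 and NR4A2 at -2.65 ± 0.87, or -1.54 without female placenta 3. Over the fits without 1 library the camera adjusted p of this list ran from 7.72e-06 to 0.956, and that of the pseudoautosomal list from 0.0438 to 0.861. Cell proliferation genes stood at -0.16 (adjusted p = 0.419), with CCNB2 at -0.80 ± 0.45, or -0.20 without female placenta 3, and KIF20A at -0.42 ± 0.29. Histone genes stood at -0.019 while their mean was 0.048 (adjusted p = 0.667), with H2AC6 at 0.93 ± 0.33 and H2AX at 0.44 ± 0.25. The ribosomal list, selected by symbol prefix, stood at 0.00058 (adjusted p = 0.895), and its 2 genes of smallest p were the kinases RPS6KA1 and RPS6KA2, at -0.51 ± 0.23 and 0.70 ± 0.39.

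The placentae varied widely within a sex, with a common biological coefficient of variation of 54.3% by edgeR. Low counts were also recorded in coarse steps that differed between libraries. On data simulated with the dispersion estimated for each gene, the test recovered 14.0% of genes changed 2-fold, 62.0% of those changed 4-fold and 82.0% of those changed 8-fold. The simulation left out the coarse steps and any shared dam, and changed only genes with higher counts.

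**Figure D3:**
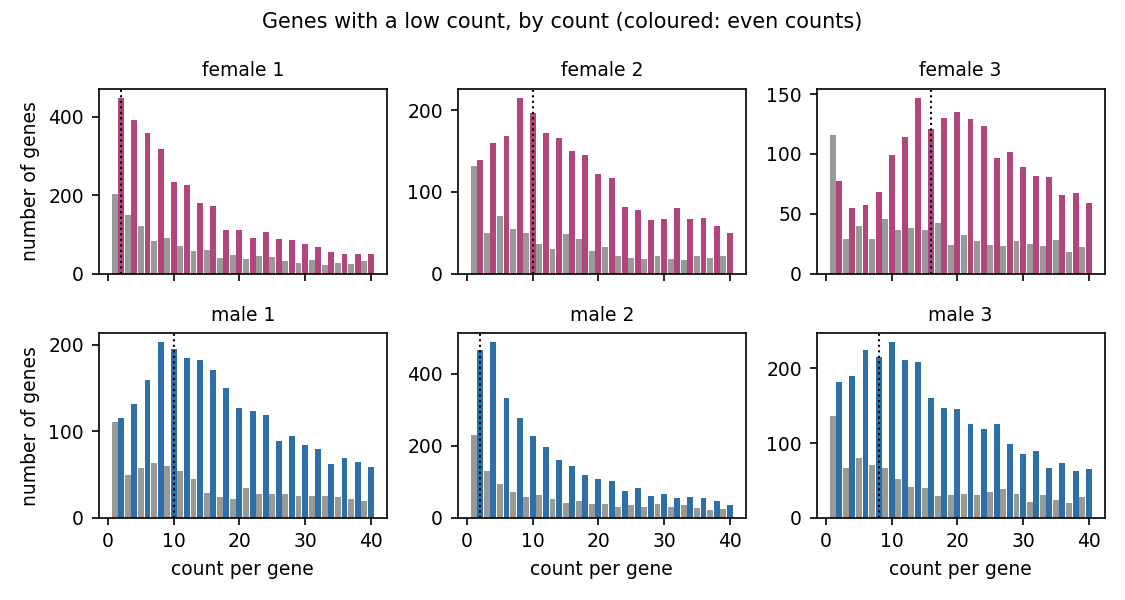
Number of genes (vertical axis) at each low count (horizontal axis) in each library, with even counts coloured and odd counts grey. Dotted lines mark the smoothed most frequent low count, which is 2 in female placenta 1 and male placenta 2 and 16 in female placenta 3.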

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

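The exact test without a filter, the divided counts, the fit without male placentae 1 and 3 and the list of all X-linked genes were chosen after the data were seen. All 6 genes called were also called with other size factors, with library sizes alone, without a filter, with a stricter filter, at an adjusted p of 0.1, with a 2-fold limit, with divided counts, in each fit without 1 library, and by DESeq2, the likelihood ratio test and the exact test. Genes counted here and below as outside the sex chromosome lists are also not placed on chromosome X or Y. The count includes genes without a symbol, whose chromosome could not be placed, among them 5 of the 6 genes called. Limma-voom called 0 genes higher, 0 outside the sex chromosome lists and 0 Y-linked, and its smallest adjusted p was 0.323. DESeq2 called 20 higher, 11 lower, 29 outside the sex chromosome lists and 2 Y-linked genes. The likelihood ratio test called 20, 4, 22 and 2 of these, and the exact test 29, 6, 33 and 2. The cause of these differences between tools was not tested.

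Leaving out 1 library at a time gave 6 to 15 genes higher, 0 to 31 lower, 5 to 35 outside the sex chromosome lists, 0 to 1 on chromosome X and 2 to 7 gene lists past camera. The highest counts of lower and of other genes came without female placenta 1. That fit called CALML5, LCN2, UPK1B and UPK3A lower in males. The highest count of higher genes came without male placenta 2, where ALB, AMBP, APOA2 and FGB were called, with 1 gene lower. Lists past camera numbered 7 without female placenta 2 and 2 without male placenta 3. The cause was not tested.

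Gene lists depended on the set test, with 0 past the threshold by camera with an estimated correlation, by fry, or by fry for mixed directions. The interferon and smooth muscle lists passed in 12 of 15 alternatives each, the 3 exceptions being these tests. The endothelial list passed in 11 and the hepatic list in 10, of which 9 were in the reported direction. Over the fits without 1 library the interferon median ran from -0.73 to -0.40. All the passes used camera at the preset correlation of 0.01, so they do not test that setting. The estimated correlation was 0.76 for smooth muscle and 0.0058 for interferon.

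Without both male placentae 1 and 3, only 1 male library remains, and it is assumed to vary like the females. The sign changed for ALB (-0.075), TF (-1.71), VTN (-1.23), FGG (-6.49), EPB42 (-1.10) and DIRAS3 (-0.31), and for the medians of the hepatic list (-6.49), the erythroid list (-0.95) and the oxidative phosphorylation list (-0.17). FGG had 0 counts in male placenta 2, and the hepatic median is its fitted value, so neither is a measure of size.

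The labels do not say that a replicate number marks a dam. Libraries sharing a number deviated from their sex's mean with correlations of 0.069, 0.22 and 0.20 across genes. The other pairs of a male and a female library had correlations of -0.19 to -0.026. The first is under the 0.1 asked of every same-numbered pair, so the numbers were not used as pairs. Since 3 dams gave the 6 libraries, some libraries share a dam. Which ones do stays open, and the main fit treats all 6 as independent. With the replicate number as a block, 5 genes were called, all among the 6, and 7 gene lists passed. As a hint from the data, the deviations of all 6 libraries correlated best with those of the library of the other sex that had their own number. With the counts divided, 12356 genes passed the filter, against 15603.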

Other observations

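The tests of fetal sex as a source of the hepatic transcripts and of fewer leukocytes, and all genes and list memberships singled out below, were chosen after the result was seen. After the values were known, 3 readings of a test were also made stricter. These were an allowance for the spread of the cartilage median, an allowance for the spread of the leukocyte and interferon medians, and a requirement that dividing the counts move the fold changes. Each of these moved the reading of its test from argued against to open.

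The most abundant transcripts with a symbol were GRN, the precursor of the granulin growth factors, at a mean of 38540 CPM over the 6 libraries, and PLET1, a placental epithelial protein, at 26072 CPM. The lysosomal protease CTSZ followed at 12745 CPM, BPI at 8953 CPM and AKR1B1, the aldose reductase that starts the path from glucose to fructose, at 7889 CPM. None differed between the sexes by edgeR, and their levels varied several-fold between libraries, for GRN from 9550 to 62901 CPM. Female placenta 3 was lowest for PLET1, at 9340 CPM against 24488 to 33595 in the other libraries. It was also lowest for AKR1B1, at 3740 CPM against 7127 to 10846. Its most abundant gene held 1.16% of its counts, against 3.68% to 5.80% in the other libraries. On the first principal component it lay apart, at a score of 122 against -53.6 to 4.77. The cause was not tested.

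Uroplakin genes were uneven among the female libraries. The uroplakins form the membrane plaques of urinary tract epithelium. UPK1B was at 319 and 293 CPM in female placentae 2 and 3 and at 16.1 in female placenta 1, with 42.7 to 84.7 CPM in males. UPK1A was at 1154 and 605 CPM in the same 2 females, 2.07 in female placenta 1 and 82.7 to 241 in males. PSCA, KLF5 and LCN2 had the same order, with PSCA at 138 and 105 CPM against 1.30. Over all 6 libraries none differed between the sexes by edgeR. Without female placenta 1, UPK1B, UPK3A, PSCA, KLF5 and LCN2 were lower in males (adjusted p from 0.00187 to 0.0416 by edgeR), and UPK1A and UPK2 did not pass. No explanation was tested.

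Hepatic transcripts in male placentae 1 and 3 and neuronal transcripts in male placenta 3 were far above the other libraries. Lists of organ markers written before the test were used, without the members that an earlier list held, which removed 5 secreted hepatic proteins after the result was seen. The 15 left were all detected and lay at a median of 4.82 log2 units higher in male placentae 1 and 3 than in the other 4 libraries. That was above all of 10000 random lists matched on expression. The random genes were drawn separately, so this does not show where the transcripts came from. The summed level of the 15 was 843 and 1652 CPM in male placentae 1 and 3 against 47.3 to 249 elsewhere. AHSG and FETUB led them, with 45165 and 25092 counts in male placenta 3. F2 went the other way, at 236 and 147 CPM in female placentae 2 and 3 and 43.7 to 67.6 CPM in males. Carry-over of fetal liver or yolk sac material could account for this list. A difference of the list shared by males is argued against, since male placenta 2 lay at -0.50 relative to females. The 10 held-out hepatocyte enzymes lay 1.98 above the other 4 libraries in male placentae 1 and 3, and 0.51 above females in male placenta 2. For these enzymes a difference shared by males stays open. The held-out neuron list, with 15 genes detected, lay 4.02 higher in male placenta 3, consistent with fetal neural material, and FOXG1, a forebrain transcription factor, had 542 counts there and 0 elsewhere. Material of the whole fetus stays open. The median in male placenta 3 was 1.70 for skeletal muscle and 1.16 for heart muscle. It was 0.065 for cartilage, under the bound set beforehand, but with a bootstrap standard error of 0.753 that reaches past it. Outside the prediction it was 4.31 for forebrain, 2.39 for hindbrain and spinal cord and 2.25 for kidney. With 3 genes detected each, it was 4.06 for neural progenitors, 3.50 for skin, -0.18 for intestine and -0.70 for lung. Random lists matched on expression to the neuron list had a median of 0.50 in male placenta 3, and no such baseline was drawn for these other organs.

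The lower smooth muscle markers of male placentae may reflect how much contractile tissue each piece held. The list mean differed by 1.75 log2 units between female placentae 1 and 2, more than the 1.11 between the sexes, as the prediction for dissection unrelated to sex asked. The largest difference between 2 males was 0.98, under that value, and the largest of several differences is set here against a difference of means. By its camera p of 5.12e-10, sex ranked first among the 10 splits of the 6 libraries for this list. The split of female placenta 1 and male placentae 1 and 3 against the rest gave a camera p of 6.49e-09. The exact permutation p of the list means was 0.2. With an estimated correlation the list did not pass camera (adjusted p = 0.637). Whether female placenta 2 alone carries the pattern cannot be told apart, since the median without it was -0.67, between the bounds set beforehand. A difference due to fetal sex itself stays open.

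The lower interferon response of male placentae held in every fit without 1 library and ranked first among the 10 splits of the 6 libraries by its camera p, but did not pass with an estimated correlation (adjusted p = 0.221) or by fry (adjusted p = 0.126). The test of fewer leukocytes does not decide, since the leukocyte median lay 0.36 above the interferon median with a bootstrap standard error of 0.226 over genes. The library means say more. Leukocyte list means were 3.21, 2.84 and 3.70 log2 CPM in female placentae 1, 2 and 3, and 2.88, 3.15 and 3.50 in the males. Female placenta 2 had the lowest of these and the highest interferon mean, 2.96. These overlapping means argue against fewer leukocytes as the source, for the cells the list marks. Coarse counts stay open. The median was -0.48 after the counts were divided, but the division moved the members by a median of only 0.019 log2 units, so it was hardly a test. A difference due to fetal sex stays open and untested beyond this comparison.

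The 10 splits of the 6 libraries into 3 and 3 are too few for a share under 0.05. Sex gave 6 genes and the highest other split 0, and 1 split of 10 reached the real count. These 6 genes were read in every male library and had at most 2 counts in any female library. Their number therefore does not tell whether sex groups the other genes. For gene lists, sex gave 4 past camera and the highest other split 10, and 7 of 10 splits reached the real count.

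The first 580 rows of the deposited table do not follow the order of gene IDs. Their position correlated with the p of an edgeR exact test at a Spearman rho of 0.80 across genes, and all 6 genes called lay among them.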
